A study of Mus musculus with 18 samples.

How the data were processed

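Total RNA was extracted with TRIzol from cultured mouse macrophages and sequenced after TruSeq directional library preparation, per the labels' protocols. The 18 libraries fall into 6 groups of 3: B6 and T169A cells, each unstimulated, with LPS for 2 hours, or with LPS/5z7 for 2 hours. The authors deposited raw counts per gene, made with Trim Galore, STAR and featureCounts on the mouse build GRCm39, per the submitters' processing notes, which give no versions, no strand setting and no treatment of reads that match several genes. Overlapping, antisense and near-identical genes are therefore uncertain. The deposited counts are whole numbers with a different total in each column.

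The deposited table has 56953 gene IDs, of which 31172 had no count in any library. Symbols, chromosomes, lengths and GC content came from GENCODE M21 on the older build GRCm38, so no coordinates are given; 52029 IDs (91.4%) matched a symbol, and these held 99.8% of the counts. The column names give the group and a running number but no replicate letter, while the sample titles give letters and no number. Columns were therefore tied to groups and not to single samples, and libraries are named by group and running number.

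Depth ran from 14.6 to 30.4 M counts per library. A floor of 3 counts corresponds to 0.0986 CPM in the deepest and 0.205 CPM in the shallowest library. Pairs of replicates differed by 2.87 to 102 times the variance of counting alone (chi-square over degrees of freedom, 1 value per pair over all genes with at least 20 counts).

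Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 13068, and libraries scaled with TMM. A quasi-likelihood model with robust estimation held 6 group means over all 18 libraries, and 12 comparisons were tested with the F-test: 3 between treatments in each genotype, 3 between genotypes, and 3 differences of effects between genotypes. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. SEs are the log2 fold change divided by the square root of F. The design, the comparisons, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

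Gene lists were tested with camera (limma 3.58.1) with its preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list; lists with fewer than 4 genes tested are given as values. They cover inflammatory cytokines, chemokines, NF-kB genes, interferon genes, MAP kinase and SRF immediate early genes, inflammatory effectors, cell death, the TLR4 and TAK1 pathway, the integrated stress response, heat shock, NRF2, cholesterol synthesis, LXR, glycolysis and hypoxia, oxidative phosphorylation, p53, proliferation, macrophage identity and surface receptors, mitochondrial transcripts, histones, markers of 8 other cell types, sex-linked genes, genes near Ripk1 and the substrain marker Nnt. Named genes are, per comparison, the 8 with the largest change in each direction among called genes whose libraries do not overlap and that reach 10 CPM, the 5 called members of each list with the smallest p and 2 abundant members not called, a fixed set that includes Ripk1, Tnf, Il1b and Mlkl, and the 8 with the smallest p in each direction for differences between genotypes.

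The analysis was tested on simulated data in 3 runs, with counts drawn independently for each library from the real means and library sizes. The tested effect was first removed from the means, and 200 of 13068 genes were then changed by known folds. For B6 LPS against unstimulated libraries, 43.8%, 73.6% and 93.4% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. The real comparison called 8240 genes, so its adjustment for multiple tests is less strict and these shares do not describe it. Alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter, a filter of 1 CPM in 3 libraries, fits on the groups compared alone, each library left out, and other fold minimums. Scaling by library size alone, a correction for transcript length, leaving out genes of the X and Y chromosomes, lists without library 7, the shares with each library left out, LPS genes taken from the other genotype, the NF-kB list with each library left out and sets of consecutive running numbers were added after the data were seen. The planned fits with the replicate letter were not run, since the columns carry no letter. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No column was left out.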

Results

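The samples were macrophages grown from mouse bone marrow for 7 days in medium with 20% fetal bovine serum and 30% supernatant of L929 cells, a source of the macrophage growth factor M-CSF. They came from C57BL/6J mice, called B6, and from mice whose Ripk1 gene carries the T169A change, called T169A; Ripk1 encodes a kinase that controls cell death and inflammatory signalling downstream of TNF and Toll-like receptors. Cells of each genotype were left unstimulated, given lipopolysaccharide (LPS, a ligand of the receptor TLR4) for 2 hours, or given LPS together with 5z7 for 2 hours. The labels do not spell out 5z7, an abbreviation in common use for (5Z)-7-oxozeaenol, an inhibitor of the kinase TAK1. The 6 groups held 3 libraries each, and gene counts were compared over 13068 genes.

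The B6 unstimulated libraries 1, 4 and 7 held 19.4, 27.4 and 14.6 M counts, the B6 LPS libraries 2, 5 and 8 held 30.0, 30.4 and 15.5 M, and the B6 LPS/5z7 libraries 3, 6 and 9 held 23.7, 18.1 and 18.1 M. The T169A unstimulated libraries 10, 13 and 16 held 19.4, 19.9 and 19.1 M, the T169A LPS libraries 11, 14 and 17 held 29.5, 18.2 and 18 M, and the T169A LPS/5z7 libraries 12, 15 and 18 held 28.5, 20.4 and 17 M. The numbers are those of the deposited columns. Lyz2, the lysozyme gene typical of macrophages, had the most counts in all 18 libraries. Nothing beyond the labels says whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples. Levels are given in counts per M (CPM, scaled by TMM) as the mean ± SD of 3 libraries, and changes as the log2 fold change ± SE.

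Ripk1 itself was present in all 18 libraries, at 89.7 ± 13.5 CPM in unstimulated B6 cells and 95 ± 3.88 CPM in unstimulated T169A cells. After LPS it stood at 85.8 ± 5.12 CPM in B6 and 79.7 ± 13.9 CPM in T169A, and with LPS/5z7 at 78.5 ± 3.03 and 71.2 ± 8.13 CPM. It was not called different between the genotypes in any condition (edgeR quasi-likelihood test, adjusted p = 1, 0.878 and 0.77 for unstimulated, LPS and LPS/5z7). A gene count does not show a single changed amino acid, so these values do not check which allele a library carries.

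The first question was what 2 hours of LPS changed in each genotype. In B6 cells, Il1b, encoding interleukin-1 beta, rose from 37.4 ± 8.32 to 7960 ± 918 CPM, a log2 fold change of 7.73 ± 0.29. Tnf rose from 106 ± 27.4 to 4950 ± 371 CPM (5.54 ± 0.23) and Cxcl10, a chemokine induced by interferon, from 22.4 ± 2.87 to 4980 ± 307 CPM (7.80 ± 0.33). Il6 went from 0.0278 ± 0.0269 to 80.1 ± 11.5 CPM, Il12b from 0.11 ± 0.109 to 307 ± 34.8 CPM and Ifnb1, the interferon-beta gene, from 0.0686 ± 0.0482 to 59.6 ± 3.46 CPM. Cxcr4, a chemokine receptor gene, fell from 368 ± 14.6 to 7.16 ± 0.392 CPM and Cnr2, the cannabinoid receptor gene of immune cells, from 25.3 ± 1.62 to 0.171 ± 0.0228 CPM. The adjusted p-values of these 8 genes lay between 2.05e-15 and 4.43e-11 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and all 3 LPS libraries lay on the same side of all 3 unstimulated ones.

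The gene groups of the inflammatory response rose together in B6. Of 20 inflammatory cytokine genes measured, 19 rose, also when adjusted over the list alone; Osm did not pass the test, but did without B6 LPS library 5 or unstimulated library 7 (edgeR adjusted p = 0.042 and 0.0254). All 17 chemokine genes rose, among them Ccl3 (6.72 ± 0.19) and Ccl4 (7.38 ± 0.24), as did all 29 NF-kB subunits and feedback regulators, among them Nfkbia (3.36 ± 0.16), Tnfaip3 (5.12 ± 0.27) and Icam1 (4.01 ± 0.14), and all 40 interferon genes, among them Mx2 (6.86 ± 0.19) and Irf1 (4.21 ± 0.13). The counts adjusted over the list alone were the same for these groups, at 17, 29 and 40. Of 26 inflammatory effector genes 25 rose (25 adjusted over the list alone), led by Ptgs2, the inducible cyclooxygenase gene (9.15 ± 0.33), while Plau stood at 258 ± 23.8 and 277 ± 7.69 CPM. These 5 lists stood apart from other genes in camera tests (adjusted p at most 5.08e-26), and the calls held with an estimated correlation (adjusted p = 0.000983 for the cytokines, 0.00136 for the chemokines, 0.00717 for NF-kB, 0.0462 for the interferon genes and 0.000983 for the effectors).

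Other groups were mixed. Among 37 MAP kinase and SRF immediate early genes 26 rose and 6 fell (27 and 8 adjusted over the list alone), with Dusp2 at 6.09 ± 0.29 and Mafk at 2.52 ± 0.13 but Fos at −3.78 ± 0.15 and Dusp6 at −3.28 ± 0.16. The camera call of this list (adjusted p = 0.00115) was lost with an estimated correlation (adjusted p = 0.266 with an estimated correlation). Of 31 TLR4 and TAK1 pathway genes 22 rose and 3 fell (22 and 3 adjusted over the list alone). Myd88 rose by 2.01 ± 0.09 and Map3k8 by 2.93 ± 0.13, and Tlr4 itself fell from 85.1 ± 29.1 to 34.0 ± 7.44 CPM (adjusted p = 0.000271, edgeR). That list's camera call (adjusted p = 0.000264) went to adjusted p = 0.224 with an estimated correlation. In the cell death list 16 of 30 genes rose and 4 fell (16 and 4 adjusted over the list alone). Casp4 (2.50 ± 0.12), Fas (2.24 ± 0.13) and Bcl2l11 (2.20 ± 0.12) rose, Casp9 (−1.82 ± 0.10) fell, and Casp8 stood at 87.9 ± 3.26 and 97.1 ± 2.46 CPM. Mlkl, the effector of necroptosis, rose by 1.96 ± 0.17, as did Zbp1, a sensor upstream of it that is not in the list (2.48 ± 0.22), while Ripk3 stood at 9.46 ± 0.936 and 9.22 ± 0.644 CPM. The cell death camera call (adjusted p = 0.0345) went to adjusted p = 0.193 with an estimated correlation, and to 0.0955 for the cell death machinery list with library size alone. That scaling also moves the list's median from 0.45 to −0.142, as its shift of all genes by −0.59 does to any list with such a median.

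T169A cells gave a like picture. Il1b rose from 27.2 ± 12.9 to 7650 ± 651 CPM (8.14 ± 0.30), Tnf from 83.1 ± 30 to 4410 ± 370 CPM (5.73 ± 0.24) and Cxcl10 from 15.5 ± 8.23 to 4430 ± 424 CPM (8.16 ± 0.33). The counts were 19 of 20 cytokine genes, 17 of 17 chemokine genes, 28 of 29 NF-kB genes, 40 of 40 interferon genes and 25 of 26 effector genes higher, and 19, 17, 29, 40 and 25 adjusted over the list alone. Cyld, an NF-kB regulator, had an adjusted p of 0.0503 (edgeR), 0.0251 without T169A LPS library 17 and 0.0287 in a fit on the groups compared alone. With sets of consecutive running numbers as a replicate block its adjusted p was 0.0165 (edgeR). The camera calls of these 5 lists held with an estimated correlation (adjusted p = 0.000221, 0.000406, 0.00185, 0.042 and 0.000406 in the same order).

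Over all genes, edgeR called 3868 higher and 4372 lower with LPS in B6 and 3965 higher and 4120 lower in T169A, of which 1894 and 1860 rose at least 2-fold. Scaled by library size alone, the splits were 1996 higher and 8484 lower in B6 and 1934 higher and 8106 lower in T169A, because that scaling shifts the median of all genes by −0.59 and −0.58 (log2). The TMM factors ran from 1.24 to 1.28 in unstimulated and from 0.83 to 0.86 in LPS libraries, so a direction given here is relative to the bulk of the genes.

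**Figure D1:**
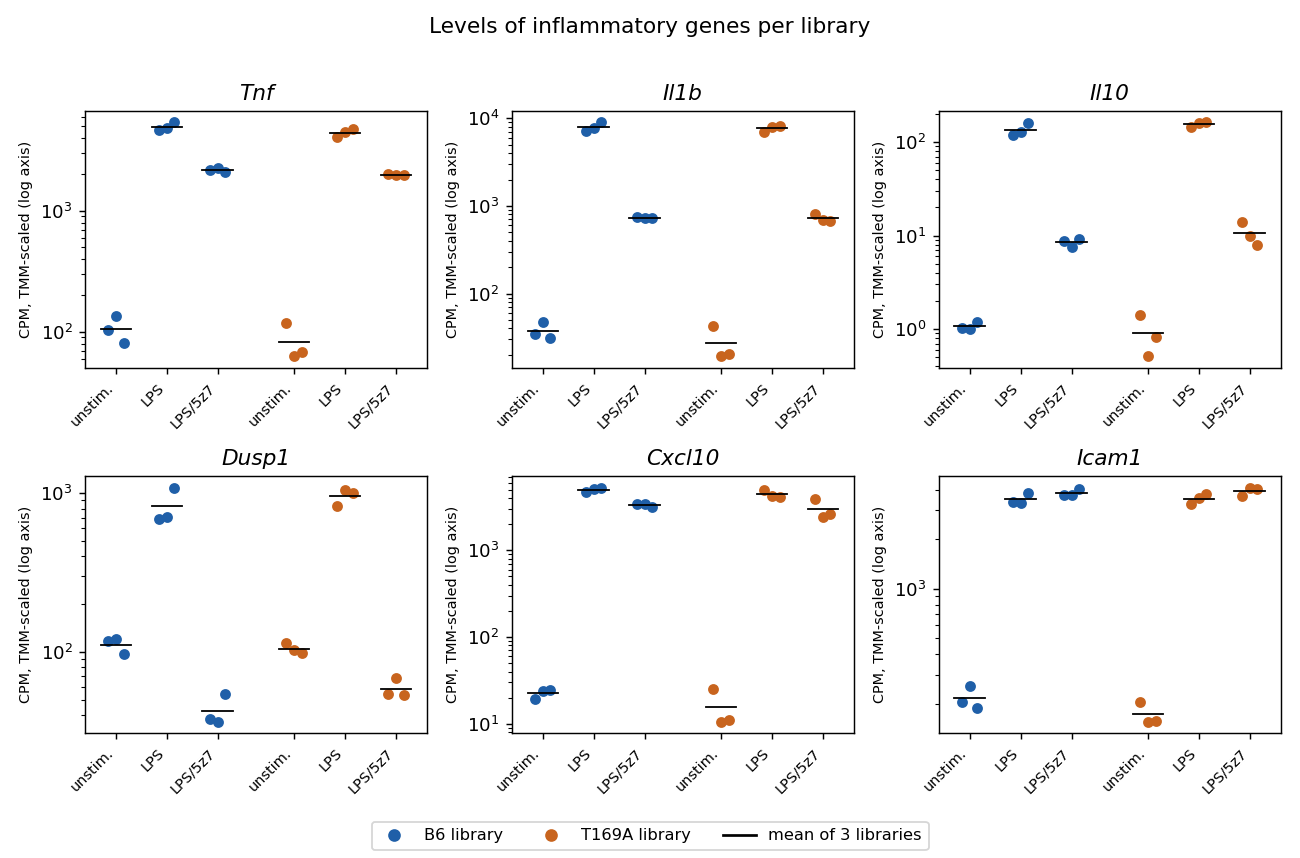
Levels of 6 genes in the 6 groups, in TMM-scaled counts per M on a log axis; each point is 1 library and each bar the mean of 3. In B6, Il1b went from 37.4 to 7960 CPM with LPS and stood at 729 CPM with LPS/5z7, while Icam1 stood at 3510 CPM with LPS and 3820 CPM with LPS/5z7.

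The second question was what 5z7 changed in cells given LPS. In B6, Il1b was at 7960 ± 918 CPM with LPS and 729 ± 7.95 CPM with LPS/5z7 (−3.45 ± 0.24), Il1a at 2660 ± 94.4 and 184 ± 15.1 CPM (−3.86 ± 0.24), and Il10, an anti-inflammatory cytokine gene, at 137 ± 21.5 and 8.54 ± 0.855 CPM (−4.00 ± 0.20). Dusp1, a phosphatase gene that limits MAP kinase activity, fell from 825 ± 222 to 42.5 ± 9.8 CPM (−4.28 ± 0.20) and Ptgs2 from 839 ± 19 to 57.2 ± 13.4 CPM (−3.88 ± 0.25). Tnf fell less, from 4950 ± 371 to 2160 ± 68.6 CPM (−1.19 ± 0.19, adjusted p = 0.000473). Cxcl10 (−0.57 ± 0.24, adjusted p = 0.137) and Icam1 (0.13 ± 0.13, adjusted p = 0.612) were not called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In a fit on the groups compared alone, Cxcl10 was called lower (−0.58, edgeR adjusted p = 0.000542). It was also called with sets of consecutive running numbers as a replicate block (−0.57, edgeR adjusted p = 0.014).

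Of 37 MAP kinase and SRF immediate early genes, 30 fell in B6 and 30 in T169A, and 0 rose (32 lower and 0 higher adjusted over the list alone in each). Phlda1 (−3.73 ± 0.27), Maff (−2.62 ± 0.18) and Zfp36, which shortens the life of cytokine mRNAs (−1.94 ± 0.15), were among them in B6. Of 20 cytokine genes 15 fell in each genotype (16 adjusted over the list alone), including Il23a (−5.29 ± 0.34), Csf2 (−4.45 ± 0.49), Lif (−3.78 ± 0.34), Osm (−3.69 ± 0.17) and Il6 (−1.92 ± 0.29) in B6. Of 17 chemokine genes 12 fell and Cx3cl1 rose in each genotype (13 lower and 1 higher adjusted over the list alone). In B6, Cxcl2 (−3.11 ± 0.24), Cxcl3 (−2.38 ± 0.15), Ccl3 (−2.24 ± 0.15) and Ccl2 (−2.09 ± 0.22) fell, while Ccl5 stood at 1570 ± 142 and 1380 ± 10.5 CPM. Of 26 effector genes 13 fell in B6 and 12 in T169A (15 lower and 1 higher, and 14 lower and 2 higher, adjusted over the list alone), among them the plasminogen system genes Plau (−2.29 ± 0.13) and Plaur (−2.36 ± 0.12) and Serpinb2 (−2.61 ± 0.19). These 4 lists were lower in camera tests, with an estimated correlation too (adjusted p = 0.000169, 7.83e-05, 0.00623 and 0.00111 in B6 and 0.000113, 7.62e-05, 0.00515 and 0.00129 in T169A).

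Of 29 NF-kB genes, 10 fell and Birc2 rose in B6, and 9 fell and Birc2 rose in T169A (14 lower and 1 higher adjusted over the list alone in each). Tnfaip3 (−1.48 ± 0.23), Tnip2 (−0.83 ± 0.10) and Nfkbia (−0.62 ± 0.15) fell in B6, and Tnfaip2, the most abundant member, stood at 11600 ± 404 and 10600 ± 390 CPM. Of 40 interferon genes 5 fell in B6 and 3 in T169A (5 and 2 adjusted over the list alone). Ifnb1 itself fell in B6 (−2.19 ± 0.17), while Rsad2 stood at 3630 ± 273 and 2750 ± 99.9 CPM (adjusted p = 0.348, edgeR) and was called lower in a fit on the groups compared alone (−0.41, edgeR adjusted p = 0.00454). Rsad2 was also called with sets of consecutive running numbers as a replicate block (edgeR adjusted p = 0.00444). Both lists were called lower by camera with its preset correlation (adjusted p = 5.7e-06 and 0.0022 in B6, 1.54e-05 and 0.00557 in T169A). Neither call held: adjusted p = 0.377 and 0.822 in B6 and 0.42 and 0.949 in T169A with an estimated correlation.

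In the list of glycolysis and hypoxia genes 5 of 18 fell in each genotype (6 in B6 and 7 in T169A adjusted over the list alone), among them in B6 Slc2a1, the glucose transporter gene (−1.26 ± 0.09), Hk2 (−1.12 ± 0.12) and Pfkfb3 (−1.05 ± 0.15). That list held with an estimated correlation (adjusted p = 0.0138 in B6 and 0.0144 in T169A). Among the genes that rose in B6 were Sik1 (1.95 ± 0.18), Efna2 (1.61 ± 0.17), Cx3cl1 (1.60 ± 0.17), Fgl2 (1.30 ± 0.18), Tlr9 (1.20 ± 0.24), Txnip (1.15 ± 0.10) and Ticam2, an adaptor of TLR4 (1.04 ± 0.09). In the cell death list 3 genes fell, among them Mcl1, a survival gene (−0.67 ± 0.10), and Nlrp3, an inflammasome sensor gene (−1.33 ± 0.24), 2 rose, among them Casp9 (0.52 ± 0.10), and 25 of 30 were not called. Its adjusted p was 0.997, and that of the TLR4 and TAK1 pathway, with 5 of 31 lower and 2 higher, was 0.34 (camera). Adjusted over the list alone, 3 cell death genes were lower and 2 higher, and 5 pathway genes lower and 2 higher. Ripk1 (−0.13 ± 0.12) and Map3k7, which encodes TAK1 (−0.06 ± 0.12), were not called.

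**Figure D2:**
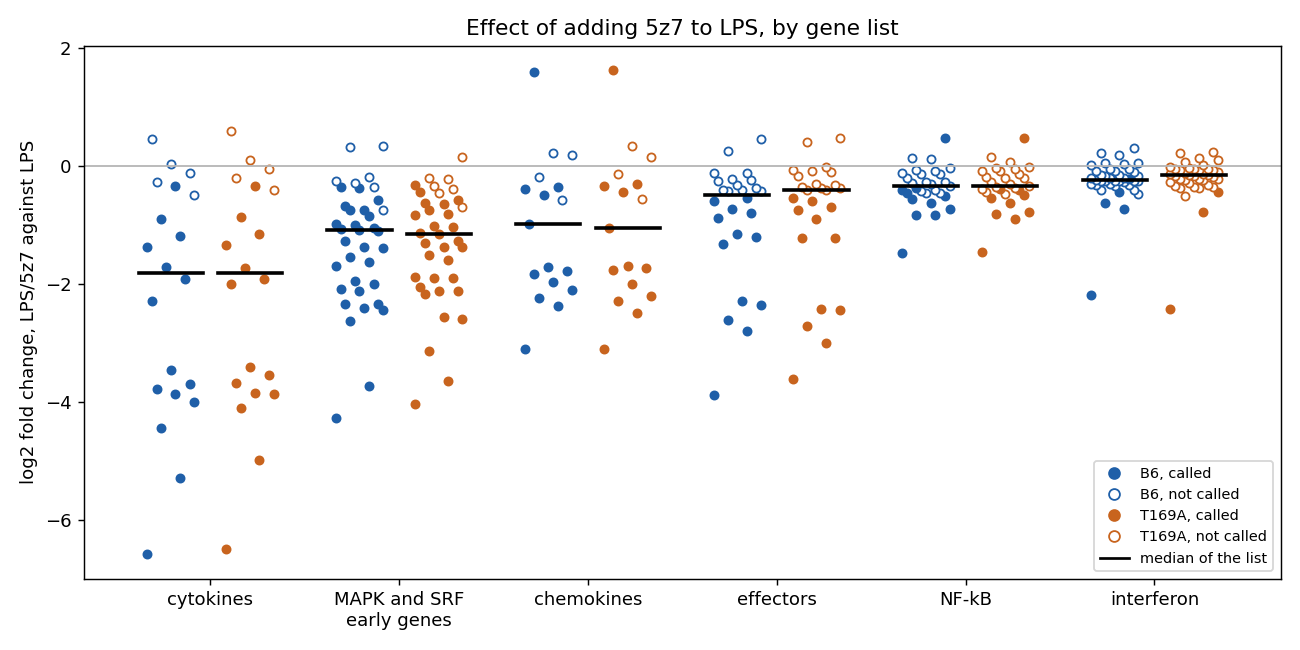
Log2 fold change of LPS/5z7 against LPS for each measured gene of 6 lists, B6 and T169A side by side; filled points passed edgeR's test at an adjusted p of 0.05, and bars mark the median of the list. The median was −1.81 for the cytokines, −1.08 for the MAP kinase and SRF genes and −0.338 for the NF-kB genes in B6.

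Over all genes, edgeR called 919 higher and 887 lower with LPS/5z7 than with LPS in B6, and 850 higher and 853 lower in T169A. Scaled by library size alone these were 2339 higher and 516 lower, and 2177 higher and 530 lower, with the median of all genes shifted by 0.16 in both. Against 1806 genes in B6, 1159 to 1275 were called whichever of the 6 libraries was left out (1159 without LPS library 5 and 1169 without LPS/5z7 library 6). In T169A, against 1703, the range was 1009 to 1634, with 1102 without LPS library 14, 1078 without LPS/5z7 library 15 and 1009 without LPS/5z7 library 18.

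Of the 1894 genes that LPS raised at least 2-fold in B6, 486 fell with 5z7 (25.7%, and 19.1 to 34.5% with 1 library left out) and 48 rose further (2.53%). In T169A 484 of 1860 fell (26.0%, and 18.6 to 26.9%) and 55 rose (2.96%). Independent lists would share 129 and 121 of the lowered genes. Of the genes that LPS lowered at least 2-fold, 458 of 2082 rose with 5z7 in B6 (22.0%) and 422 of 1997 in T169A (21.1%), while 45 and 50 fell further. Independent lists would share 146 and 130 of the raised genes. Both comparisons use the same LPS libraries, so the LPS genes were also taken from the other genotype, which shares no library. Of the T169A genes raised by LPS 497 of 1860 (26.7%) then fell with 5z7 in B6, and of the B6 genes 471 of 1894 (24.9%) in T169A, where independent lists would share 126 and 124.

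Against unstimulated cells, LPS/5z7 still left the response largely raised. In B6, Tnf stood at 4.34 ± 0.22, Cxcl10 at 7.23 ± 0.32, Il1b at 4.28 ± 0.25 and Nos2, the inducible nitric oxide synthase gene, at 9.49 ± 0.28 above unstimulated cells on the log2 scale. All 17 chemokine, 29 NF-kB and 40 interferon genes were higher in both genotypes, also adjusted over the list alone, and 18 of 20 cytokine genes in B6 and 17 in T169A (18 and 17 adjusted over the list alone). Osm was lower than in unstimulated cells (−3.45 ± 0.17 in B6 and −3.56 ± 0.17 in T169A), as were the immediate early genes Fos (−4.86 ± 0.16) and Jun (−3.70 ± 0.15) in B6. In all, 3610 genes were higher and 3647 lower in B6, and 3678 higher and 3591 lower in T169A (edgeR), against 2075 and 7334, and 1975 and 6999, with library size alone, whose median shifts were −0.43 and −0.42.

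The third question was whether T169A cells differed from B6 cells in the same condition. Gdf3, a growth factor gene of the TGF-beta family, was lower in T169A in all 3 conditions: 20.1 ± 0.983 against 5.76 ± 0.136 CPM in unstimulated cells (−1.80 ± 0.11), and −1.49 ± 0.11 with LPS and −1.73 ± 0.11 with LPS/5z7. Axl, a receptor for apoptotic cells, was lower too (−0.89 ± 0.13, −1.07 ± 0.13 and −1.08 ± 0.13), as was Marco, a scavenger receptor gene (−1.14 ± 0.15, −1.10 ± 0.14 and −0.95 ± 0.14). Cx3cr1, the fractalkine receptor gene, stood at 191 ± 14.9 CPM in unstimulated B6 and 115 ± 6.53 CPM in unstimulated T169A cells (−0.73 ± 0.08). Tgfbi, Col18a1, Plxdc2, Wdfy1 and Mtus2 were lower in all 3 conditions as well, and Camk2b was higher, at 2.38 ± 0.661 against 0.364 ± 0.0675 CPM in unstimulated cells. Mtus2 was low in B6 (1.79, 0.906 and 1.38 CPM in unstimulated, LPS and LPS/5z7 cells). In T169A it lay near or under the floor of 3 counts (0.0535, 0.0216 and 0.105 CPM), so the size of its change is uncertain.

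These 10 genes are the autosomal ones called in the same direction in all 3 conditions (edgeR, largest adjusted p 0.0111); Camk2b, Col18a1, Mtus2 and Tgfbi lie outside the naming rule and were chosen after their values were seen. Independent lists of autosomal genes would share 1.9e-05 lower and 5.6e-07 higher genes, but the titles carry the same letters in all 3 conditions of a genotype, so the 3 lists may not be independent. In fits on the groups compared alone, 8 of the 10 lost the call in unstimulated cells (edgeR adjusted p = 0.403 for Axl, 0.469 for Marco, 0.299 for Col18a1, 0.115 for Cx3cr1, 0.0831 for Plxdc2 and for Tgfbi, 0.076 for Wdfy1 and 0.0712 for Camk2b). With LPS, Camk2b (0.0587), Col18a1 (0.113) and Tgfbi (0.201) did. Without a filter on low counts, Col18a1 (0.069) and Tgfbi (0.235) were lost with LPS/5z7. With LPS/5z7, Col18a1 was lost without any 1 of libraries 6, 9, 12, 15 and 18 (adjusted p = 0.0502 to 0.0899) and Tgfbi without any 1 of libraries 3, 9, 12, 15 and 18 (adjusted p = 0.0563 to 0.143). Ptges, the prostaglandin E synthase gene (−0.87 ± 0.12), and Mmp14 (−0.83 ± 0.11) were called lower in unstimulated cells alone, and not in the fit on the groups compared alone (adjusted p = 0.513 and 0.403, edgeR). The difference of LPS effects between the genotypes, tested below for all genes, was not called by edgeR for Ptges or Mmp14 in the main fit. With the length trend within groups removed, which shrinks their spread, it was called for Ptges (0.74, edgeR adjusted p = 0.0295). In that fit Ptges was also called for the difference of LPS/5z7 against unstimulated (0.79, edgeR adjusted p = 0.00978).

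Slc7a2, an arginine transporter gene of the effector list, was called lower in T169A with LPS (224 ± 45.4 against 109 ± 21.6 CPM, −1.04 ± 0.17, edgeR adjusted p = 0.00868) and with LPS/5z7 (−1.03 ± 0.17, 0.00981), and not in unstimulated cells (−0.38 ± 0.21, 1). The call with LPS was lost without library 2, 5, 14 or 17 (adjusted p = 0.072, 0.0698, 0.108 and 0.0833) and in the fit on the groups compared alone (0.187). The call with LPS/5z7 was lost without library 3, 6, 15 or 18 (0.0534, 0.087, 0.0849 and 0.119). For Slc7a2 too, edgeR did not call the difference of LPS effects between the genotypes. The genes Tnf, Il1b, Il6 and Cxcl10 were not called: with LPS, T169A against B6 gave −0.17 ± 0.19 for Tnf, −0.06 ± 0.22 for Il1b, −0.49 ± 0.27 for Il6 and −0.17 ± 0.24 for Cxcl10 (edgeR adjusted p = 0.878, 0.948, 0.876 and 0.881). Ripk3 (0.34 ± 0.13), Mlkl (−0.20 ± 0.16), Casp8 (0.02 ± 0.08) and Zbp1 (−0.08 ± 0.21) were not called either (adjusted p = 0.747, 0.876, 0.944 and 0.924).

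In all, edgeR called 10 genes higher and 18 lower in T169A in unstimulated cells, 11 and 18 with LPS, and 8 and 13 with LPS/5z7. The sexes were not matched: all 9 B6 libraries carried Xist, the RNA of the inactive X chromosome (442 to 1200 CPM before TMM scaling), and all 9 T169A libraries the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. These sex-linked genes form the only list that camera called with an estimated correlation (adjusted p = 4.07e-11 unstimulated, 1.37e-10 with LPS and 4.06e-10 with LPS/5z7). With the preset correlation, the cholesterol synthesis list was lower in T169A in all 3 conditions (adjusted p = 2.3e-07, 1.44e-10 and 2.88e-08), with medians of −0.208, −0.281 and −0.21, and adjusted p = 0.144, 0.0703 and 0.151 with an estimated correlation. In the same way, interferon genes were lower in all 3 conditions (adjusted p = 3.61e-10, 5.74e-05 and 0.00125, medians −0.308, −0.149 and −0.148), and adjusted p = 0.312, 0.684 and 0.809 with an estimated correlation. NF-kB genes (median −0.241, adjusted p = 1.06e-09), chemokines (−0.333, 0.00183; −0.352, 0.446 without B6 library 7) and effectors (−0.282, 6.67e-06) were lower in unstimulated cells, and effectors with LPS (−0.101, 0.0226), by camera with its preset correlation. Those calls were lost too, at adjusted p = 0.19, 0.312, 0.144 and 0.509 with an estimated correlation. Of the libraries left out in turn, only T169A library 10 gave an NF-kB call with an estimated correlation (median −0.408, camera adjusted p = 0.0358). Without library 1, 4, 7, 13 or 16 it was 0.251 to 0.424. Of the 20 cholesterol synthesis genes, Cyp51 was called with LPS (−0.52 ± 0.09) and none in the other conditions, against 2, 11 and 8 for unstimulated, LPS and LPS/5z7 adjusted over the list alone; its call was lost without library 2, 5 or 17 (edgeR adjusted p = 0.0528, 0.0964 and 0.0833) and in the fit on the groups compared alone (0.122).

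Neither Ripk1 nor any of the 28 measured genes near it on chromosome 13 was called in any condition. Nnt, whose loss marks C57BL/6J mice, lay near the detection limit, with a median of 0.22 CPM. Sex and genotype cannot be told apart in any of these 3 comparisons. DESeq2 called 69, 56 and 47 genes where edgeR called 28, 29 and 21, fits on the groups compared alone called 7, 13 and 223, and single libraries moved the counts: 46 unstimulated calls without B6 library 7 and 45 without T169A library 10, and with LPS 18, 16, 17 and 19 without libraries 2, 5, 14 and 17.

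**Figure D3:**
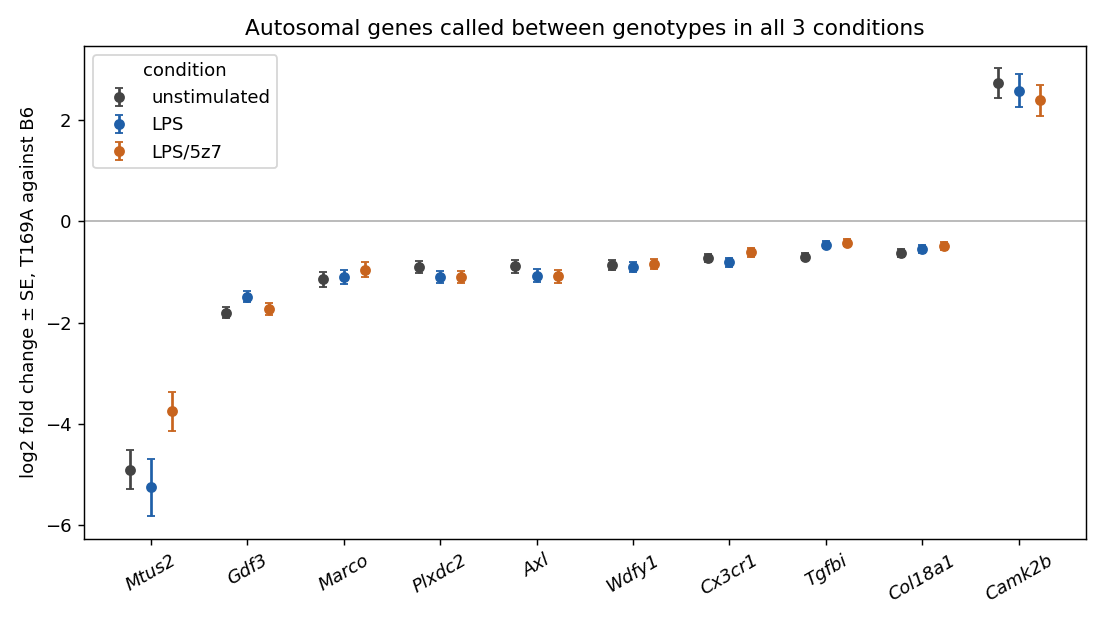
Log2 fold change of T169A against B6, with its SE, in unstimulated, LPS and LPS/5z7 cells for the 10 autosomal genes called in all 3 conditions, 3 libraries per group. Gdf3 lay at −1.80, −1.49 and −1.73, and Camk2b alone lay above 0. The T169A levels of Mtus2 were near or under the floor of 3 counts, so the size of its change is uncertain.

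The fourth question was whether the response itself differed between the genotypes, tested as the difference between the effects in T169A and B6. Sex goes with genotype here as well, so these tests cannot tell sex and mutation apart. The responses ran closely side by side. For LPS the log2 fold changes of 13068 genes had Pearson's r = 0.963 and Spearman's rho = 0.938 between the genotypes, which share no library, and 7143 of the 7144 genes called in both went the same way (independent lists would share 1174 higher and 1378 lower). For LPS/5z7 against LPS, r was 0.727 and rho 0.73, and all 1319 genes called in both went the same way (60 and 58 by chance). Genes are not independent replicates, so these values carry no p.

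For single genes, the difference was 0.19 ± 0.27 for Tnf, 0.41 ± 0.32 for Il1b and 0.36 ± 0.35 for Cxcl10 in the effect of LPS, and 0.04 ± 0.27, 0.05 ± 0.31 and 0.01 ± 0.34 in the effect of adding 5z7 (log2, T169A minus B6). Among the genes with the smallest p for the effect of LPS were Ptges (0.74 ± 0.16), Tarm1 (1.10 ± 0.24), Saa3, an acute phase gene (2.06 ± 0.56), Hp (1.24 ± 0.33) and Serpinb2 (−1.24 ± 0.36), each at an adjusted p of 0.916. edgeR's quasi-likelihood test called 0 genes for the effect of LPS, 0 for the effect of adding 5z7 and 0 for LPS/5z7 against unstimulated, with 421, 151 and 461 genes at an unadjusted p under 0.05. These are 3.22, 1.16 and 3.53% of the genes tested, less than the share of 0.05 that would fall there if no gene differed. DESeq2 called 0, 0 and 2: Ptges (0.79, adjusted p = 0.0083) and 1 gene without a symbol, both named after their values were seen. On simulated counts the test for the effect of adding 5z7 recovered 12.4% of genes changed 1.5-fold, 51.2% of those changed 2-fold and 85.9% of those changed 4-fold, so small differences would mostly be missed. The simulated libraries were drawn independently, while deviations of real libraries from their group means were correlated. These shares therefore need not hold for the real test, and larger differences may have been missed too.

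**Figure D4:**
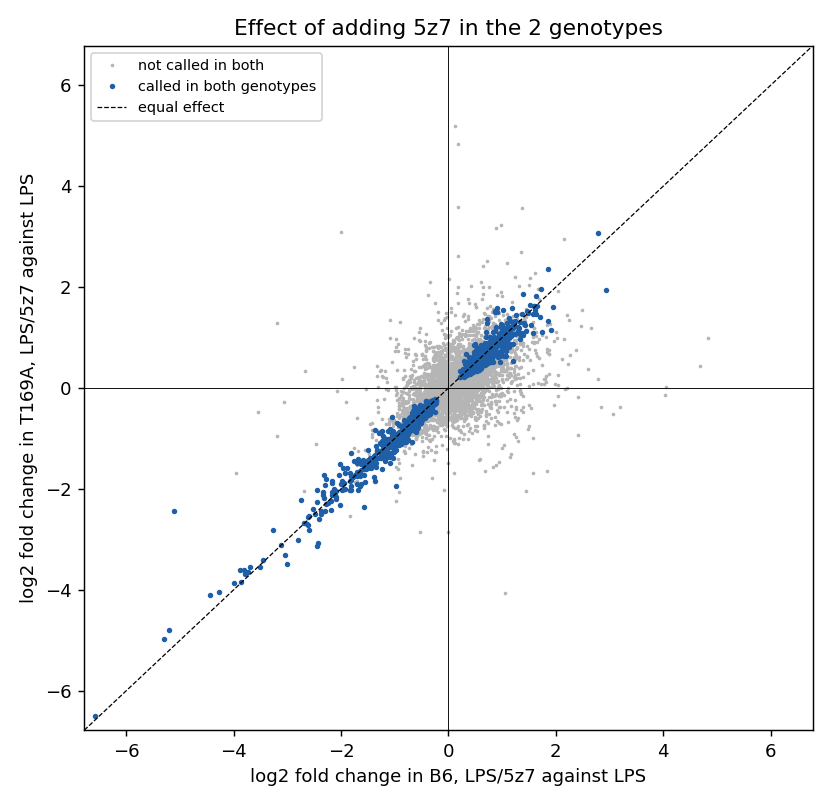
Log2 fold change of LPS/5z7 against LPS in B6 (horizontal axis) and T169A (vertical axis), 1 point per gene over 13068 genes. The 1319 genes called in both genotypes are drawn dark and all lie in the lower left or upper right part of the plot.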

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

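The tests of sex, chromosome, macrophage share, transcript length, depth, activation and library 7, and the splits for the NF-kB median and for length-corrected counts, were chosen after the results were seen; the other splits were planned.

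For differences between T169A and B6 in the effects of treatment, camera with its preset correlation gave 7 calls of gene lists. For LPS against unstimulated these were chemokines (median difference 0.22, adjusted p = 0.0429), NF-kB genes (0.25, 2.97e-07), oxidative phosphorylation (0.21, 0.000152) and histones (0.48, 0.0284). For LPS/5z7 against unstimulated they were NF-kB genes (0.28, 2.4e-07), effectors (0.19, 0.0413) and oxidative phosphorylation (0.22, 4.07e-05). NF-kB genes and oxidative phosphorylation were called in both comparisons. These share the unstimulated libraries, so the second call of a list is not independent of the first. None of the 7 calls held with an estimated correlation (camera adjusted p = 0.723 for the first 4 and 0.694 for the last 3). Without B6 unstimulated library 7 the calls of chemokines (median 0.287, adjusted p = 0.625), oxidative phosphorylation (0.0429, 0.658) and histones (0.24, 0.133) for LPS, and of oxidative phosphorylation for LPS/5z7 (0.0705, 0.251), were lost, the chemokine median not being smaller; by the preset correlation calls were gained for effectors (0.194, 0.00118), neutrophil markers (−0.559, 0.00173), NRF2 (0.167, 0.0129) and MAP kinase genes (0.173, 0.04) with LPS, and NRF2 (0.192, 0.00156), neutrophil markers (−0.43, 0.00387) and glycolysis and hypoxia (0.105, 0.0379) with LPS/5z7.

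As a list, NF-kB genes were called higher in the difference of LPS effects, and lower in unstimulated T169A cells (median −0.24), by camera's preset correlation alone: with an estimated correlation adjusted p = 0.723 and 0.19, and edgeR called 0 of the 29 genes for the difference. Library 7 did not enlarge the median difference, which was 0.25 with it and 0.32 without it (camera adjusted p without it = 1.28e-16 with the preset correlation, 0.437 with an estimated one). With the trend over transcript length taken out, the median was 0.24 (camera adjusted p = 1.71e-05 with the preset correlation). That correction was fitted within groups and leaves the group means almost as they were. It therefore cannot decide whether a length trend between groups contributed. Of the unstimulated T169A libraries, 10 lay above 13 and 16 on this list (median deviations 0.232, −0.135 and −0.127). Without 10 the unstimulated median was −0.408 and the difference 0.425 (camera adjusted p = 0.0358 and 0.126 with an estimated correlation). Without T169A library 13 or 16 the unstimulated median was −0.188 and −0.151. Without B6 library 4 it was −0.146, with a difference of 0.188. The lower level therefore rests mostly on T169A libraries 13 and 16 and on B6 library 4. With each library left out the difference ran from 0.179 to 0.425. Chance could not be excluded: 23 of 100 splits of the samples gave a median as far from 0 (real 0.25, highest other 0.45), and 15 of 100 for LPS/5z7 against unstimulated (0.28, highest other 0.4). A true difference of the mutant cells, or of their sex, may remain, and neither was tested apart from this.

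Axl, Cx3cr1, Gdf3, Marco and 6 other autosomal genes differed between the genotypes in all 3 conditions. Variants carried beside the Ripk1 allele cannot act on their neighbours in 9 of the 10, which lie on other chromosomes. For Tgfbi, on the same chromosome, the test leaves this open, with 0 of 28 genes near Ripk1 called. Summed before TMM scaling, genes near Ripk1 stood higher in T169A in each condition. The sums were 2060 ± 36.9 against 1930 ± 85 CPM unstimulated, 1450 ± 7.43 against 1350 ± 28 with LPS and 1550 ± 12.7 against 1420 ± 14.7 with LPS/5z7. A smaller share of macrophages was argued against by 21 other macrophage identity genes, whose lowest median over the conditions was −0.03, against −0.89 for the 9 lower genes in unstimulated cells; of the other cell markers above 10 CPM in sum in unstimulated T169A cells, 3 lists stood higher than in B6, neutrophil (71.2 against 54 CPM) and fibroblast (15.8 against 9.45) with camera calls (adjusted p = 1.37e-05 and 0.00367) lost at adjusted p = 0.147 and 0.264 with an estimated correlation, and osteoclast markers (135 against 115) with none, and whether such cells account for the 10 genes was not tested. Sex cannot be told apart from genotype, because the 2 go together in all 18 libraries. The mutation, the sex of the animals and variants beside Ripk1 or elsewhere in the genome may each explain these genes. Effects of variants beside Ripk1 on genes of other chromosomes were not tested.

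B6 unstimulated library 7 lay apart from libraries 1 and 4, with deviations of an SD of 0.343. The trend over annotated length did not account for all of this, since the SD was 0.228 with the length trend taken out, against at most 0.158 in the other libraries. Length was that of the longest annotated transcript of a gene, which need not be the one expressed. Whether loss of long transcripts was the whole cause therefore cannot be decided. Counting error from lower depth was argued against by a chi-square over degrees of freedom of 81.6. Partial activation of the culture was argued against too, since LPS-induced genes lay below repressed ones (−0.174, against up to 0.181 in T169A unstimulated libraries). Each value is relative to the other libraries of the group, and B6 library 4 itself stood at 0.163. Other libraries lay apart from their mates too, B6 8 and 9 (chi-square at least 22.6 and 11.7, against 5.9 and 5.1 between the mates) and T169A 11 and 12 (27.7 and 20.4, against 7.55 and 2.87), so this is not particular to library 7, and the animal, culture or handling of the RNA may remain untested causes.

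For 9 counts of genes called between pairs of groups, 10 splits of 6 samples are too few for a share under 0.05. As many genes were called in 1 split, the real one, and the highest other gave 0, for LPS (8240 in B6, 8085 in T169A), LPS/5z7 against LPS (1806 and 1703), LPS/5z7 against unstimulated (7257 and 7269), and T169A against B6 with LPS (29) and LPS/5z7 (21). For T169A against B6 in unstimulated cells 2 splits did (real 28, highest other 80). For the differences of effects, chance cannot be excluded: 56, 96 and 40 of 100 splits gave as many genes at an unadjusted p under 0.05 (real 421, 151 and 461, highest others 5617, 4430 and 3521). The real counts were no excess to begin with, at 3.22, 1.16 and 3.53% of the genes tested. With the length trend removed, 47 and 25 of 100 splits called as many genes for LPS and LPS/5z7 against unstimulated (real 51 and 261, highest others 4986 and 3209). Splits that call many times the real count point to a structure of the samples, whose cause was not tested.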

How the results depend on the processing

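Scaling by library size, the length correction, leaving out X and Y genes, lists without library 7, shares with each library left out, LPS genes from the other genotype, the NF-kB list with each library left out and sets of consecutive numbers were chosen after the data were seen; the rest was planned. Of 99 counts of called genes under other settings, 83 stayed within 1.5 times the main count.

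For T169A against B6 (28, 29 and 21 genes in unstimulated, LPS and LPS/5z7 cells), DESeq2 called 69, 56 and 47, fits on the groups compared alone 7, 13 and 223, and no filter 39 with LPS/5z7. Without X and Y genes 13 were called with LPS/5z7; of the 21, 14 are autosomal. Removing the length trend gave 77, 103 and 346, and 51 and 261 for the difference of effects of LPS and of LPS/5z7 against unstimulated (0 and 0 in edgeR, 421 and 461 at an unadjusted p under 0.05); fitted within groups, it shrinks their spread. DESeq2 called 2 for the latter. For LPS/5z7 against LPS, library size alone gave 2855 in B6 and 2707 in T169A (median shift 0.16). For LPS in B6, it reversed Casp8 (−0.45), Osm (−0.36) and Plau (−0.49), not called by edgeR with TMM over all libraries, since that scaling shifts all genes by −0.59. Except for these constructions, the cause was not tested.

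The share of LPS-induced genes lowered by 5z7 (25.7% in B6, 26.0% in T169A) was 28.1% in B6 with DESeq2 size factors, 17.9 and 16.8% with no fold minimum, 30.2 and 30.8% with a 4-fold minimum, and 26.7 and 24.9% with LPS genes from the other genotype. The correlation between genotypes was 0.975 for LPS and 0.835 for adding 5z7 with a filter of 1 CPM in 3 libraries, against 0.963 and 0.727; the cause was not tested.

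With each library left out, counts ran from 22 to 46 (T169A against B6 unstimulated), 16 to 33 (LPS) and 15 to 19 (LPS/5z7), from 1159 to 1275 (LPS/5z7 against LPS, B6) and 1009 to 1634 (T169A), from 7573 to 8609 and 7465 to 7755 (LPS), and from 6522 to 7625 and 6376 to 6770 (LPS/5z7 against unstimulated); shares ran from 19.1 to 34.5% (B6) and 18.6 to 26.9% (T169A). The differences of effects stayed at 0 by edgeR. Without library 7 the oxidative phosphorylation list, T169A against B6 unstimulated, reversed, from a median of −0.117 to 0.0555 (camera adjusted p = 0.109). Depth limits genes under about 0.205 CPM, 3 counts in the shallowest library.

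The columns carry no replicate letter, so the planned fits with the letter were not run. Their running numbers follow the order of the sample list, so sets of 3 consecutive numbers may be replicates, which no label says. Deviations from group means correlated over 0.1 in 16 of 18 pairs of these sets (−0.05 to 0.71, and 0 for libraries 13 and 14). They were highest within the set in 24 of 36 cases, more often than a random pick among 3 libraries would give, which goes with pairing. Correlations between genotypes, which share no set, reached 0.77. Since no label gives the pairing, the main fit left the sets out, and they were used as an alternative. With them as a replicate block, edgeR called 8788 and 8651 genes for LPS in B6 and T169A, 2447 and 2340 for LPS/5z7 against LPS, 7921 and 7951 for LPS/5z7 against unstimulated and 0 for each difference of effects; shares were 34.1 and 34.2%. Rsad2 and Cxcl10 (LPS/5z7 against LPS, B6) and Cyld (LPS, T169A) gained a call (adjusted p = 0.00444, 0.014 and 0.0165), and no other named gene changed. As a random effect (limma), they gave 29, 29 and 23 genes between genotypes. Summed per set, 18 genes were called, 8 of the 10 of all conditions among them, without Cx3cr1 (adjusted p = 0.0771) and Col18a1 (0.08).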

Other observations

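Beyond the inflammatory genes, LPS changed growth, stress and metabolism genes in B6. Mki67, a proliferation marker, rose from 43.5 ± 20.2 to 481 ± 95.1 CPM (3.46 ± 0.29), while the replication genes Mcm7 (−1.04 ± 0.14), Mcm2 (−0.81 ± 0.12) and Mcm3 (−0.67 ± 0.09) fell; in all 2 of 25 proliferation genes rose and 12 fell (camera adjusted p = 0.35). Hspa1b (4.63 ± 0.19) and Hspa1a (3.68 ± 0.14) led the heat shock list, with 8 of 14 higher and 2 lower (adjusted p = 0.00693, and adjusted p = 0.0382 with an estimated correlation); with library size alone, which shifts all genes by −0.59, the heat shock response list had a median of −0.16 in place of 0.43 and an adjusted p of 0.0576. Slc7a11, a cystine transporter gene (5.20 ± 0.44), and Txnrd1 (2.45 ± 0.21) rose among 15 NRF2 targets, 4 higher and 4 lower (adjusted p = 0.889). Hk2 (2.42 ± 0.13) and Slc2a1 (1.86 ± 0.09) rose among the 18 genes of glycolysis and hypoxia, 9 higher and 2 lower (adjusted p = 0.0114, and adjusted p = 0.16 with an estimated correlation), for which that scaling gave a median of −0.34 in place of 0.252 and an adjusted p of 0.0662. Of 20 cholesterol synthesis genes 9 rose and 4 fell (0.344). Abcg1 (−1.15 ± 0.12) fell among 10 LXR targets, 1 higher and 5 lower (0.0947; 0.0362 without B6 unstimulated library 7).

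Cdkn1a, a p53 target, rose from 352 ± 11.7 to 3480 ± 440 CPM with LPS in B6 while Sesn1 fell from 202 ± 30.7 to 11.1 ± 2.46 CPM; 3 of 12 p53 targets rose and 5 fell (camera adjusted p = 0.662). Adding 5z7 lowered Gdf15 (−2.68 ± 0.23), Mdm2 (−1.64 ± 0.12) and Plk2 (−1.55 ± 0.18) and raised Sesn1 (1.05 ± 0.19) in B6, with 5 lower and 3 higher of 12 (adjusted p = 0.00363, and adjusted p = 0.0302 with an estimated correlation; in T169A 0.000536 and 0.0107). The median of the p53 targets list was −0.04 in B6, and 0.12 with library size alone, which shifts all genes by 0.16 here. The integrated stress list had 13 of 22 genes higher and 3 lower with LPS in B6 (adjusted p = 0.0345, adjusted p = 0.343 with an estimated correlation, and 0.0543 with library size alone).

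Cx3cr1 (−1.68 ± 0.09) fell with LPS in B6 among 22 macrophage identity genes, 6 higher and 7 lower (0.455). Of 13 surface receptors 4 rose and 5 fell (0.455), of 26 oxidative phosphorylation genes 5 rose and 1 fell (0.658), of 7 mitochondrial transcripts 5 rose (0.565), and of 4 histones 1 fell (0.565). Summed markers of other cells were low before TMM scaling: in unstimulated B6 neutrophil 54.0, B cell 31.2, T and NK cell 5.71, dendritic cell 67.6, fibroblast 9.45, erythroid 0.922, mast cell 0.324 and osteoclast 115 CPM, against 76800 CPM of macrophage identity genes. In camera tests of LPS in B6, 5 of 8 neutrophil (0.565), 7 of 7 dendritic cell (0.163), 1 of 6 fibroblast (0.658) and 3 of 6 osteoclast genes (0.171) were higher; the B cell (2), T and NK (1), erythroid (1) and mast cell lists (1) had too few genes tested. Between genotypes neutrophil (median 0.68, adjusted p = 1.37e-05) and fibroblast genes (0.73, 0.00367) were higher in unstimulated T169A cells, and adjusted p = 0.147 and 0.264 with an estimated correlation. So were neutrophil genes with LPS (0.338, 0.0416) and LPS/5z7 (0.379, 0.0489) and fibroblast genes with LPS (1, 0.00149), and adjusted p = 0.643, 0.809 and 0.422 with an estimated correlation; library size alone gave 0.0531 and 0.0552 for the neutrophil genes. Summed osteoclast markers stood at 135 ± 11, 166 ± 7.82 and 194 ± 4.1 CPM in T169A against 115 ± 2.9, 149 ± 1.16 and 171 ± 2.09 CPM in B6 (unstimulated, LPS and LPS/5z7), with no camera call (adjusted p = 0.164, 0.502 and 0.84). Summed fibroblast markers stood at 15.8 ± 5.14, 15.5 ± 3.91 and 18 ± 1.02 against 9.45 ± 2.24, 9.44 ± 0.947 and 15.9 ± 3.61 CPM.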
